A study of Homo sapiens with 18 samples.

How the data were processed

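RNA sequencing values of 16 H929 and MM1S libraries and of 2 RIP libraries from MM1S were used as deposited; raw reads were not used here. Per the labels, RNA was taken up in TRIzol and libraries were made with a SMARTER mRNA kit. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' notes list the mouse builds GRCm38 and mm10, although the cells and the gene symbols are human, so no coordinates are printed. The H929 table and the RIP table hold FPKM, as made by the authors: the file names or headers say so, and column totals (374512 to 428099 in H929, 481761 and 652727 in the RIP table) differ between columns. Both MM1S expression tables are named FPKM by the authors, but their deposited values are TPM, since every column sums to between 999999 and 1000001. The design had assumed FPKM in all tables; the same test was run on the TPM values. Values from different tables were never tested against each other, since each was normalized on its own.

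Columns were matched to samples by number, and 0 columns were left unmatched. The H929 table has 16532 genes, of whose symbols 98.4% are in the human gene reference; for the MM1S tables this share is 63.9% and for the RIP values 88.2%. In the MM1S tables, 834 and 473 rows carry no gene name and hold 0.436% to 0.459% and 0.174% to 0.237% of TPM; 27 names were turned into dates and 1533 entries repeat a symbol. Relative depth in H929 was read from the steps of low FPKM values, which are whole multiples of 1 read: with scramble replicate 1 as reference the other libraries had 1.1, 0.97, 1.15, 1.11 and 1.07 times its depth. TPM keeps no such steps, and in the RIP table only 2.4% of genes sat at the most frequent ratio, so depth is unknown there. No counting interval is given for any value, since counts were not used here.

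Groups follow the labels. "In" in the labels was read as indisulam from the description of the design. The labels give no dose or time, and do not say whether the MM1S numbers 1 and 2 are hairpins or replicates; they were taken as replicates. The numbers were not used to pair libraries: the deviations of libraries with the same number correlated at 0.129, 0 and 0.025 in H929, at -0.142 in the MM1S knockdown and at 0.137, -0.148 and -0.025 with indisulam, and not every library correlated best with its own number. H929 groups were never regrouped, although the RBM39 values go against the labels.

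Each comparison was fitted with limma 3.58.1 (trend and robust) in R 4.3.3 on log2(value + 1), two-sided, for genes with a value of at least 1 in as many libraries as the smaller group holds. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. RBM39 and MAP2K5 also had exact permutation tests. The comparisons, tests, 28 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names RBM39 and MAP2K5, then the 8 genes per direction with the largest absolute log2 fold change among those called, with a group mean of at least 5, non-overlapping groups and a proper symbol, and up to 3 called members of each list by adjusted p; for overlaps up to 10 genes; for RIP the 10 highest and 5 lowest ratios. Some genes that this rule names are not reported here. Chance alone makes 10% of genes non-overlapping with 3 against 3 libraries. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, when at least 5 members were tested. List medians are relative to the median of all genes tested. Alternatives were camera with an estimated correlation and fry.

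Overlaps between comparisons used Fisher's exact test among genes tested in both. RIP ratios are log2((RBM39 + 1)/(IgG + 1)) for genes at 1 FPKM or more in either library, and list medians were ranked among 10000 random lists matched on mean expression in 20 bins. The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5, quantile normalization, median scaling, limma without trend and robust, a replicate block, a log2 change of at least 1, and leaving out each library in turn. Leaving a library out of the MM1S knockdown leaves 1 library in a group, which is then assumed to vary like the other group. Added after the data were seen were a crossed replicate block, list tests and overlaps without indisulam replicate 3, and 4 gene lists. The naming of genes called in both MM1S comparisons, or in both and opposite in H929, was also added then. The pipeline was tested on simulated data with the size and spread of each comparison and 200 changed genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, it called 81.8%, 100% and 100% in H929. It called 0%, 0% and 19% in the MM1S knockdown, and 1.5%, 39.4% and 80.6% with indisulam. In the data far more genes were called, 7477, 1461 and 4024. The adjusted p depends on how many genes change, so these shares do not give the power in the data. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.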

Results

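The data were 18 sequencing libraries from H929 and MM1S, established human multiple myeloma cell lines. RNA sequencing covered 16 of them. In H929, 3 libraries labelled scramble stood against 3 labelled shRBM39. In MM1S, 2 scramble libraries stood against 2 shRBM39 libraries, and 3 DMSO libraries against 3 treated with indisulam. The other 2 libraries were RNA immunoprecipitations (RIP) from MM1S, 1 with an antibody to RBM39 and 1 with control IgG. RBM39 is an RNA-binding protein that takes part in pre-mRNA splicing, and indisulam is a sulfonamide that brings the RBM39 protein to the DCAF15 ubiquitin ligase for degradation. Depth could be compared only within the H929 table, where the other 5 libraries had 0.97 to 1.15 times the depth of scramble replicate 1; it is unknown for the MM1S and RIP libraries. Genes are named by symbol, as in the files. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical in part.

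The first question was whether the transcripts of RBM39 and of MAP2K5, which encodes the kinase MEK5, changed. In H929, RBM39 was 4.5 ± 0.0631 FPKM (mean ± SD, n = 3) in the libraries labelled scramble and 37.5 ± 1.66 FPKM (n = 3) in those labelled shRBM39, a log2 difference of 2.81 (SE 0.055, limma adjusted p = 7.68e-13). This direction is opposite to the one the labels name. All 3 libraries labelled shRBM39, at 35.6 to 38.6 FPKM, lay above all 3 labelled scramble, at 4.43 to 4.56 FPKM. The H929 groups are therefore given below as labelled, with no statement on which group had less RBM39 protein. In MM1S, RBM39 fell from 190.4 ± 20 TPM (n = 2) with scramble to 58.5 ± 8.89 TPM (n = 2) with shRBM39, a log2 change of -1.69 (SE 0.161, limma adjusted p = 0.0121). With indisulam, RBM39 transcript was 197.8 ± 42.1 TPM (n = 3) against 187.6 ± 8.89 TPM (n = 3) in DMSO, a log2 difference of 0.05 (SE 0.16, limma adjusted p = 0.828). Without indisulam replicate 3, in which RBM39 was 149.4 TPM, that difference was 0.24 (limma adjusted p = 0.00899).

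MAP2K5 was lower in the H929 libraries labelled shRBM39, at 1.64 ± 0.0815 FPKM against 2.42 ± 0.11 FPKM (n = 3 each), a log2 difference of -0.37 (SE 0.0682, limma adjusted p = 2.74e-04), or -0.24 relative to the median of all genes tested. It did not pass the test in MM1S. There it was 8.05 ± 1.85 TPM with scramble and 9.64 ± 0.368 TPM with shRBM39 (n = 2 each), a log2 difference of 0.25 (SE 0.204, limma adjusted p = 0.451). It was 10.95 ± 0.649 TPM in DMSO and 9.08 ± 1.1 TPM with indisulam (n = 3 each), a log2 difference of -0.25 (SE 0.158, limma adjusted p = 0.266), and -0.32 without indisulam replicate 3 (limma adjusted p = 0.026). Two-sided exact permutation tests gave p = 0.1 for both genes in H929, 0.333 for both in the MM1S knockdown, and 0.9 for RBM39 and 0.1 for MAP2K5 with indisulam. The smallest exact p that 3 against 3 libraries allow is 0.1, and 2 against 2 allow 0.333, so these tests could not reach 0.05.

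**Figure D1:**
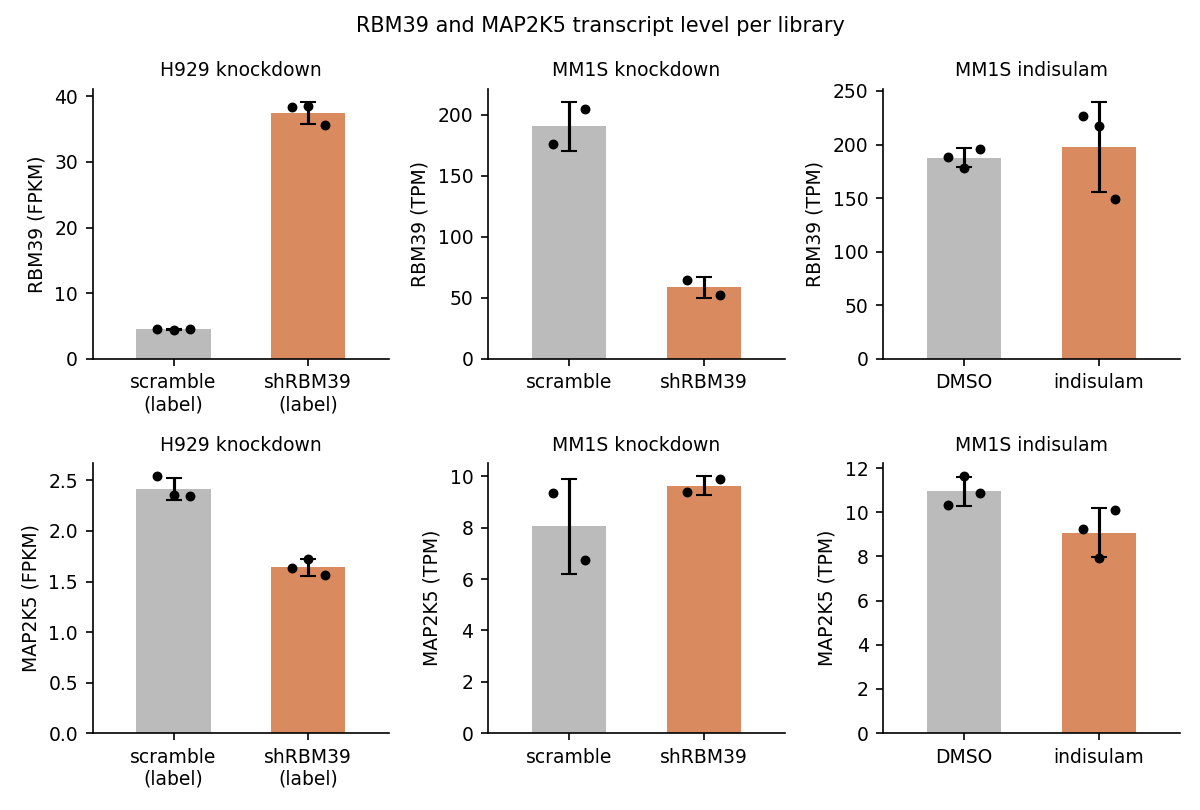
Expression of RBM39 and MAP2K5 in each library, in FPKM for H929 and TPM for MM1S; bars are group means, error bars are SD and points are libraries. RBM39 was higher in the H929 libraries labelled shRBM39 (37.5 against 4.5 FPKM) and lower in the MM1S shRBM39 libraries (58.5 against 190.4 TPM).

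The H929 comparison was meant to ask what knockdown of RBM39 does to gene expression in that line. Since RBM39 was higher in the libraries labelled shRBM39, the values below are not read as effects of knockdown. The genes with the largest higher values in the libraries labelled shRBM39, after RBM39 itself, were SCD, a fatty acid desaturase, at 95.5 ± 1.66 against 14.8 ± 0.118 FPKM (mean ± SD, n = 3 each), PPFIA4 at 9.11 ± 1.55 against 0.977 ± 0.0262 FPKM, and HPRT1, a purine salvage enzyme, at 36.5 ± 1.56 against 6.99 ± 0.485 FPKM. CA9, a carbonic anhydrase induced by hypoxia, was at 6.63 ± 0.361 against 0.672 ± 0.143 FPKM. The plasma cell surface marker SDC1 was at 500.2 ± 5.72 against 124.6 ± 5.47 FPKM, the glycolytic regulator PFKFB4 at 13.5 ± 3.19 against 2.62 ± 0.354 FPKM, and the ribonucleotide reductase subunit RRM2 at 109 ± 6.24 against 28.3 ± 1.15 FPKM. The largest lower values were those of the protease inhibitor SLPI, at 0.739 ± 0.283 against 22.7 ± 3.87 FPKM, the mucin MUC13, at 2.59 ± 0.189 against 37.2 ± 0.571 FPKM, and MYOF, at 1.58 ± 0.217 against 25.6 ± 0.713 FPKM. The chemokine gene CCL4 was at 0.687 ± 0.165 against 13.3 ± 1.53 FPKM, and CDKN1A, which encodes the cell cycle inhibitor p21, at 126.3 ± 3.74 against 747.8 ± 32.6 FPKM. DMBT1 was at 0.775 ± 0.3 against 13 ± 2.42 FPKM, the TWEAK receptor gene TNFRSF12A at 3.97 ± 0.242 against 28.6 ± 2.4 FPKM and EVC at 10.6 ± 1.54 against 65.1 ± 2.87 FPKM.

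Several gene groups moved together in H929. All 40 tested genes of cytosolic ribosomal proteins were higher in the libraries labelled shRBM39 (40 adjusted over the list alone; camera adjusted p = 5.91e-17, adjusted p = 0.343 with an estimated correlation), among them RPL3, at 2239 against 970.2 FPKM. Of 19 genes of glycolysis, 15 were higher and 3 lower, with the same 15 and 3 adjusted over the list alone (camera adjusted p = 2.14e-06, adjusted p = 0.343 with an estimated correlation). ENO1 was at 1525 against 539.9 FPKM and PGK1 at 337.4 against 126.4 FPKM, while the glucose transporter gene SLC2A1 was lower, at 45.3 against 153.2 FPKM. Of 20 plasma cell identity genes, 15 were higher and 4 lower, 15 and 4 adjusted over the list alone (camera adjusted p = 2.14e-06, adjusted p = 0.113 with an estimated correlation), with MZB1 at 515.2 against 236.4 FPKM. Of 27 interferon response genes, 20 were higher and 5 lower, 20 and 5 adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.343 with an estimated correlation), with the antiviral gene MX1 at 107.6 against 45.8 FPKM. DNA replication genes were higher in 20 and lower in 6 of 38 cases, 20 and 6 adjusted over the list alone (camera adjusted p = 3.49e-05, adjusted p = 0.397 with an estimated correlation).

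Higher groups also included the unfolded protein response, with 16 of 28 genes higher and 6 lower (camera adjusted p = 7.96e-04, adjusted p = 0.343 with an estimated correlation), where the ER-associated degradation gene DERL3 was at 59.9 against 17.9 FPKM. Nuclear genes of oxidative phosphorylation were higher in 17 and lower in 2 of 32 cases (camera adjusted p = 1.82e-04, adjusted p = 0.397 with an estimated correlation). MYC and nucleolar genes were higher in 12 and lower in 2 of 26 cases (camera adjusted p = 7.18e-04, adjusted p = 0.397 with an estimated correlation). Cholesterol synthesis genes were higher in 12 and lower in 7 of 23 cases (camera adjusted p = 0.0126, adjusted p = 0.343 with an estimated correlation), with SQLE lower, at 12.1 against 24.9 FPKM. For these 4 lists the counts adjusted over the list alone were the same, at 16 and 6, 17 and 2, 12 and 2, and 12 and 7. After median scaling they were 20 and 2, 27 and 1, 20 and 1, and 14 and 2, and for DNA replication 27 and 1.

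The lower groups in H929 held targets of p53, of ATF4 and of NF-kB, and genes listed for the MEK5-ERK5 pathway, its own kinases included. Of 23 p53 targets, 22 were lower and 1 higher, 22 and 1 adjusted over the list alone (camera adjusted p = 7.02e-06, adjusted p = 0.343 with an estimated correlation), with the death receptor gene TNFRSF10B at 26 against 92.7 FPKM. Of 27 ATF4 targets of the integrated stress response, 23 were lower and 2 higher, 23 and 2 adjusted over the list alone (camera adjusted p = 3.49e-05, adjusted p = 0.343 with an estimated correlation), among them the amino acid transporter gene SLC7A5, at 85.5 against 240.2 FPKM, and the serine synthesis gene PHGDH, at 12.5 against 38 FPKM. Of 14 NF-kB targets, 12 were lower, 12 adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.397 with an estimated correlation), with BIRC3 at 0.75 against 4.54 FPKM. Of 15 MEK5-ERK5 pathway genes, 14 were lower, 14 adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.258 with an estimated correlation). These included the nuclear receptor gene NR4A1, at 1.88 ± 0.122 against 10.5 ± 0.226 FPKM, FOSL1, at 2.08 ± 0.274 against 6.01 ± 0.303 FPKM, and SQSTM1, at 66.1 ± 2.09 against 118.8 ± 4.05 FPKM (n = 3 each); after median scaling 10 of the 15 were called lower.

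The remaining lists did not pass the set test in H929. BCL2 family genes were lower in 10 of 14 cases (camera adjusted p = 0.0562), with the pro-apoptotic genes BBC3 at 3.64 against 17.6 FPKM and BCL2L11 at 5.66 against 20.5 FPKM. Proteasome subunit genes were lower in 17 and higher in 3 of 32 cases (camera adjusted p = 0.536), but 9 lower and 11 higher after median scaling. Core splicing factors were higher in 15 and lower in 19 of 42 cases, mitosis genes higher in 12 and lower in 14 of 34, and homologous recombination genes higher in 8 and lower in 8 of 30. RAS-ERK feedback targets were higher in 4 and lower in 8 of 16 cases, components of the DCAF15 ligase higher in 2 and lower in 6 of 11, heat shock genes higher in 5 and lower in 8 of 15, and histone genes higher in 3 and lower in 8 of 11. Adjusted over the list alone these counts were the same, apart from 9 lower heat shock genes. The balance of several lists turned after median scaling, to 22 higher and 11 lower splicing factors, 15 and 9 mitosis genes, 15 and 4 homologous recombination genes, 6 and 4 heat shock genes and 3 and 2 DCAF15 ligase components. It stayed on the lower side for RAS-ERK feedback targets (5 and 8), the BCL2 family (2 and 6) and histones (3 and 7). Markers of other cell types were too few for a set test. The T cell gene CD3E was at 17 against 42.9 FPKM, the macrophage marker CD68 at 13.8 against 25.5 FPKM, the smooth muscle actin gene ACTA2 at 5.6 against 16.5 FPKM and GATA3 at 1.96 against 12.9 FPKM, all lower in the libraries labelled shRBM39, as were 2 of 3 B cell markers, FCER2, at 0.531 against 2.4 FPKM, and BANK1, at 1.15 against 1.71 FPKM. The B cell gene CD79B was higher, at 55.4 against 46.1 FPKM. The H929 table lists no mitochondrially encoded genes.

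In the limma test, 7477 of 10360 genes passed in H929, 2498 higher and 4979 lower in the libraries labelled shRBM39. The median log2 difference of all genes tested was -0.134, and the share of calls that were higher, 33.4% as deposited, was 54.3% after median scaling and 49.6% after quantile normalization. None of the camera calls on the lists fixed beforehand held with an estimated correlation, in any of the 3 comparisons. The set test covered 22 lists in H929 and 23 in each MM1S comparison. With an estimated correlation, camera has only the few residual degrees of freedom of each fit, so small p-values are hard to reach. The loss alone therefore does not show that correlation between genes made the calls. The H929 plasma cell identity list lost its call at an estimated correlation of -0.0119 (camera adjusted p = 0.113). Other lists had estimated correlations far above the preset 0.01. These were 0.785 for ribosomal proteins in H929, 0.599 for mitosis in the MM1S knockdown and 0.543 for DNA replication with indisulam, for example. For such lists the p-values at the preset correlation may be too small.

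The MM1S knockdown comparison asked what knockdown of RBM39 does to gene expression in a line where the RBM39 transcript fell. The largest decreases included cytokine genes and a feedback regulator of cytokine signalling. The chemokine gene CCL4 fell from 438.1 ± 90.6 to 12.1 ± 5.64 TPM, and SOCS3, which restrains JAK-STAT signalling, from 28.7 ± 4.14 to 0.4 ± 0.269 TPM (mean ± SD, n = 2 each). The chemokine gene CCL3L1 fell from 1110 ± 539 to 130.8 ± 47.8 TPM, CXCL13 from 65.5 ± 46.5 to 6.34 ± 3.38 TPM, and the interleukin gene IL10 from 80.8 ± 80.3 to 0.55 ± 0.311 TPM, the last with an SD near its mean. PCLAF, a PCNA-binding factor, fell from 86.2 ± 2.45 to 11.3 ± 9.48 TPM. SLX1B, from 23.3 to 1.81 TPM, has the near-identical paralog SLX1A, so reads may be shared between them. The largest increases outside pseudogenes were in the aldehyde dehydrogenase gene ALDH8A1, from 0.515 ± 0.106 to 10.7 ± 1.51 TPM, COX7C, a subunit gene of cytochrome oxidase, from 118.2 ± 9.52 to 650.4 ± 1.21 TPM, and the light chain segment IGLV6-57, from 8.16 ± 0.962 to 49.2 ± 3.19 TPM. ERMN rose from 2.22 ± 0.622 to 15.7 ± 0.198 TPM, PGM5 from 1.11 ± 0.481 to 11.5 ± 7.47 TPM and LHFPL2 from 4.27 ± 1.44 to 24.6 ± 3.12 TPM. The pseudogene SNRPGP15, with the largest increase of all named genes, was listed at 0 with scramble and at 11.2 TPM with shRBM39. The pseudogene PPIAP22 rose from 0.795 ± 1.12 to 11.2 ± 3.59 TPM. LINC02008 was listed at 7.79 TPM with scramble and at 0 with shRBM39.

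Cell division genes fell as a group. Of 34 mitosis genes, 33 fell, or 34 adjusted over the list alone (camera adjusted p = 5.88e-22, adjusted p = 0.823 with an estimated correlation), among them the anaphase activator gene CDC20, from 91.6 ± 1.27 to 20.8 ± 1.85 TPM, cyclin B1 (CCNB1), from 161 ± 3.58 to 46.2 ± 0.184 TPM, and UBE2C, from 204.2 ± 5.03 to 64.1 ± 0.099 TPM (n = 2 each). Of 38 DNA replication genes, 29 fell, or 38 adjusted over the list alone (camera adjusted p = 8.79e-18, adjusted p = 0.823 with an estimated correlation), including the helicase genes GINS4, from 27.3 to 5.51 TPM, and MCM4, from 224.9 to 65 TPM. Of 32 homologous recombination and Fanconi genes, 17 fell, or 22 adjusted over the list alone (camera adjusted p = 4.99e-08, adjusted p = 0.823 with an estimated correlation), including FANCI, from 140.3 to 37.8 TPM. Of 19 glycolysis genes, 7 fell and 1 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 5.22e-04, adjusted p = 0.823 with an estimated correlation), with LDHA from 1379 to 517.5 TPM. Of 23 cholesterol synthesis genes, 4 fell, or 10 adjusted over the list alone (camera adjusted p = 2.78e-04, adjusted p = 0.982 with an estimated correlation). Of 23 p53 targets, 4 rose, 4 adjusted over the list alone (camera adjusted p = 0.0314, adjusted p = 0.823 with an estimated correlation), among them ZMAT3, from 4.14 to 15.5 TPM, BBC3, from 7.46 to 26.1 TPM, and the death receptor gene FAS, from 23.3 to 60.8 TPM.

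The MEK5-ERK5 list did not pass in the MM1S knockdown (camera adjusted p = 0.983; its median log2 change relative to all genes was 0.08 and its mean -0.19). SGK1 fell from 215.7 ± 61.6 to 52.3 ± 20.7 TPM and NR4A1 from 10.4 ± 4.67 to 1.97 ± 1.09 TPM, while SQSTM1 rose from 134.7 ± 16.8 to 238.8 ± 27.6 TPM (n = 2 each). In all, 3 of 14 members fell and 1 rose, 3 and 1 adjusted over the list alone. Among RAS-ERK feedback targets, 2 of 12 fell, including cyclin D2 (CCND2), from 375.2 to 65.9 TPM. Of 32 proteasome subunit genes, 0 passed limma's test over all genes or over the list alone, and their median log2 change was -0.07. Of 42 core splicing factors, 3 rose and 4 fell, RBM39 among the latter, and SF3B1 rose from 93 to 197.9 TPM. Interferon response genes passed in 4 of 21 cases, 2 in each direction, and HERC5 fell from 26.8 to 3.2 TPM. NF-kB targets rose in 1 and fell in 2 of 16 cases, plasma cell identity genes rose in 1 and fell in 2 of 21, BCL2 family genes rose in 2 of 13, and unfolded protein response genes rose in 3 and fell in 3 of 28. Members that fell numbered 4 of 32 for oxidative phosphorylation, 1 of 26 each for ATF4 targets and for MYC and nucleolar genes, 1 of 11 for the DCAF15 ligase, 1 of 40 for ribosomal proteins and 1 of 13 for mitochondrial transcripts. Among 6 histone genes 1 rose, and of 16 heat shock genes 0 passed limma's test. Adjusted over the list alone, counts differed for splicing factors (4 rose), the DCAF15 ligase (3 fell), the unfolded protein response (4 rose), interferon response genes (5 fell), ribosomal proteins (0 fell) and histones (1 fell). Of other cell markers, CD3E fell from 5 to 0.915 TPM, and none of the monocyte, stromal, epithelial or B cell markers passed over all genes. Immunoglobulin transcripts made up 8.03% and 7.93% of TPM in the shRBM39 libraries against 4.76% and 5.58% with scramble.

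In the limma test, 1461 of 14152 genes passed, 562 higher and 899 lower with shRBM39. These calls rest on 2 libraries per group: 0 genes passed limma without scramble replicate 1, scramble replicate 2 or shRBM39 replicate 2 (2296, 2424 and 4605 at an unadjusted p under 0.05), 465 without shRBM39 replicate 1, and 0 with no filter on low values (4966 unadjusted).

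The indisulam comparison asked what the drug does in MM1S. The largest decreases included genes that supply or drive DNA synthesis. RRM2 fell from 158.9 ± 9.02 to 13.2 ± 1.82 TPM, thymidylate synthase (TYMS) from 214.2 ± 10.7 to 18.9 ± 3.47 TPM, and the origin licensing gene CDC6 from 27.6 ± 2.25 to 1.85 ± 0.463 TPM (mean ± SD, n = 3 each). MIR210HG, the host gene of a microRNA induced by hypoxia, fell from 131.3 ± 9.73 to 2.67 ± 1 TPM, the cytidine deaminase gene APOBEC3B from 100.2 ± 6.71 to 9.05 ± 0.288 TPM, and the checkpoint ATPase gene TRIP13 from 50.4 ± 1.4 to 4.64 ± 1.09 TPM. HES6 fell from 112.9 ± 7.51 to 11.5 ± 2.64 TPM. The largest increases outside multi-copy genes and pseudogenes were in ALDH8A1, from 0.33 ± 0.288 to 16.9 ± 1.03 TPM, and the immunoglobulin heavy chain gene IGHA1, from 1.32 ± 0.317 to 20 ± 3.54 TPM. ERMN rose from 1.83 ± 0.277 to 16.4 ± 5.06 TPM, the endogenous retroviral gene ERV3-1 from 7.72 ± 1.59 to 48.6 ± 7.99 TPM and the peptide transporter gene SLC15A2 from 3.18 ± 0.773 to 23.2 ± 10.2 TPM. The multi-copy 5S ribosomal RNA gene RNA5S4 was listed at 0 in DMSO and at 117.3 TPM with indisulam, and RNA5S8 at 91.1 TPM and at 0.

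All 38 DNA replication genes fell, 38 adjusted over the list alone (camera adjusted p = 4.97e-19, adjusted p = 0.444 with an estimated correlation), with the sliding clamp gene PCNA from 242.7 to 42.8 TPM. Of 34 mitosis genes 19 fell, 19 adjusted over the list alone (camera adjusted p = 3.05e-06, adjusted p = 0.647 with an estimated correlation), including the kinase gene AURKB, from 129 to 23.8 TPM, and TOP2A, from 64.2 to 10.6 TPM. Of 32 homologous recombination and Fanconi genes 16 fell, 16 adjusted over the list alone (camera adjusted p = 4.08e-04, adjusted p = 0.647 with an estimated correlation). Of 19 glycolysis genes 15 fell, or 18 adjusted over the list alone (camera adjusted p = 3.72e-09, adjusted p = 0.372 with an estimated correlation), among them LDHA, from 886.5 ± 93.3 to 110.1 ± 12.9 TPM, and GAPDH, from 4185 ± 53.5 to 1348 ± 80.2 TPM (n = 3 each). Of 23 cholesterol synthesis genes 15 fell, or 17 adjusted over the list alone (camera adjusted p = 3.36e-05, adjusted p = 0.472 with an estimated correlation). Of 26 MYC and nucleolar genes 16 fell, or 19 adjusted over the list alone (camera adjusted p = 3.96e-05, adjusted p = 0.472 with an estimated correlation). Of 22 p53 targets 10 rose, 10 adjusted over the list alone (camera adjusted p = 4.14e-05, adjusted p = 0.492 with an estimated correlation), among them MDM2, the ubiquitin ligase gene that restrains p53, from 81.5 to 264.6 TPM, and CCNG1, from 59.5 to 197.1 TPM.

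Proteasome genes fell with indisulam in 28 of 32 cases, or 29 adjusted over the list alone (camera adjusted p = 6.03e-09, adjusted p = 0.222 with an estimated correlation). PSMC5 fell from 168.7 ± 3.78 to 84.1 ± 5.09 TPM, PSMB7 from 203.4 ± 9.89 to 90.8 ± 9.14 TPM and PSMC3 from 150 ± 1.83 to 83.2 ± 0.584 TPM (n = 3 each). Of 32 oxidative phosphorylation genes 17 fell, or 19 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.444 with an estimated correlation). NDUFB8, a complex I subunit gene, fell from 309.1 to 61.7 TPM, and 8 members were lower and 2 higher after median scaling. Ribosomal protein genes passed the set test upwards (camera adjusted p = 0.00103, adjusted p = 0.851 with an estimated correlation), with 4 of 40 higher, 1 adjusted over the list alone and 0 after median scaling. That test was lost without indisulam replicate 3 (camera adjusted p = 0.921), in which ribosomal protein genes took 29% of TPM against 21.2% to 23% in the other 5 libraries.

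The MEK5-ERK5 list did not pass with indisulam (camera adjusted p = 0.1085). Of 12 members, 3 rose and 1 fell, 3 and 1 adjusted over the list alone, with NR4A1 rising from 1.72 ± 0.203 to 6.86 ± 0.664 TPM and KLF2 falling from 12.9 ± 1.45 to 4.33 ± 0.617 TPM (n = 3 each). After median scaling 6 members were higher and 2 lower, and without indisulam replicate 3, 9 were higher and 3 lower (camera adjusted p = 0.107). Of 42 core splicing factors, 14 fell and 3 rose (camera adjusted p = 0.272), among them U2AF1, a factor that recognises the 3' splice site, from 135.6 to 51.7 TPM, HNRNPA1, from 1203 to 571.4 TPM, and PUF60, from 96.1 to 63.1 TPM. Without indisulam replicate 3, 16 splicing factors were lower and 15 higher (camera adjusted p = 0.63). The balance of all genes turned as well. With all libraries 2885 of 13445 were lower and 1139 higher, and without replicate 3, 3959 of 14238 were lower and 5391 higher. The splicing list median relative to all genes was -0.14 with all libraries and -0.09 without replicate 3. Of the DCAF15 ligase components, 4 of 11 fell, and DCAF15 itself went from 30.9 ± 0.512 to 18.2 ± 2.19 TPM. Unfolded protein response genes rose in 5 and fell in 8 of 28 cases, with HERPUD1 rising from 493.9 to 998.7 TPM. ATF4 targets rose in 4 and fell in 3 of 26 cases, with SLC3A2 rising from 208.7 to 487.5 TPM and DDIT4 falling from 66.7 to 10.3 TPM. Plasma cell identity genes rose in 1 and fell in 6 of 20 cases, with TNFRSF13B falling from 374 to 142.4 TPM, and interferon response genes rose in 1 and fell in 8 of 17. RAS-ERK feedback targets rose in 2 and fell in 2 of 12 cases, NF-kB targets rose in 2 and fell in 2 of 15, BCL2 family genes rose in 4 and fell in 3 of 13, heat shock genes rose in 1 and fell in 3 of 15, histone genes rose in 3 of 8, and mitochondrial transcripts rose in 1 and fell in 3 of 13. Adjusted over the list alone, counts differed for splicing factors (15 fell), the BCL2 family (5 fell), plasma cell identity (2 rose, 7 fell), NF-kB targets (1 rose, 1 fell), interferon response genes (2 rose, 9 fell) and mitochondrial transcripts (2 rose). After median scaling the unfolded protein response had 4 higher and 2 lower members, interferon response genes 4 and 7, NF-kB targets 3 and 0, the BCL2 family 5 and 1, ATF4 targets 4 and 4, RAS-ERK feedback targets 3 and 4, and mitochondrial transcripts 0 and 0 by limma. Splicing factors then had 4 and 14, plasma cell identity 1 and 4, the DCAF15 ligase 1 and 3, heat shock genes 2 and 3 and histones 3 and 0. Without indisulam replicate 3, the unfolded protein response had 11 higher and 11 lower members, plasma cell identity 8 and 7, the BCL2 family 5 and 5, the DCAF15 ligase 4 and 5, ATF4 targets 8 and 3, and interferon response genes 5 and 10. RAS-ERK feedback targets then had 4 and 3, NF-kB targets 3 and 4, heat shock genes 4 and 4, histones 4 and 2, and mitochondrial transcripts 3 and 6. Of other cell markers, CD3E fell from 3.35 to 1.18 TPM and the fibronectin gene FN1 from 7.32 to 3.42 TPM. Immunoglobulin transcripts made up 14.9% to 16.6% of TPM with indisulam against 11.8% to 11.9% in DMSO.

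In the limma test, 4024 of 13445 genes passed with indisulam, 1139 higher and 2885 lower; the higher share was 28.3% as deposited and 46.7% and 52.1% after median scaling and quantile normalization. Indisulam replicate 3 stood apart, with a correlation of 0.958 and 0.964 to replicates 1 and 2, which correlated at 0.987 with each other. Without it 9350 genes passed, 57.7% of them higher, and without DMSO replicate 1, 2 or 3 the count was 2045, 1974 and 1849. Without indisulam replicate 3, 38 of 38 DNA replication genes were lower, 30 proteasome genes were lower and 1 higher, 18 glycolysis genes were lower and 1 higher, and 17 p53 targets were higher and 1 lower. Mitosis genes were then lower in 25 cases and higher in 5, homologous recombination genes lower in 16 and higher in 4, cholesterol synthesis genes lower in 17 and higher in 3, MYC and nucleolar genes lower in 19 and higher in 3, and oxidative phosphorylation genes lower in 25 and higher in 3.

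**Figure D2:**
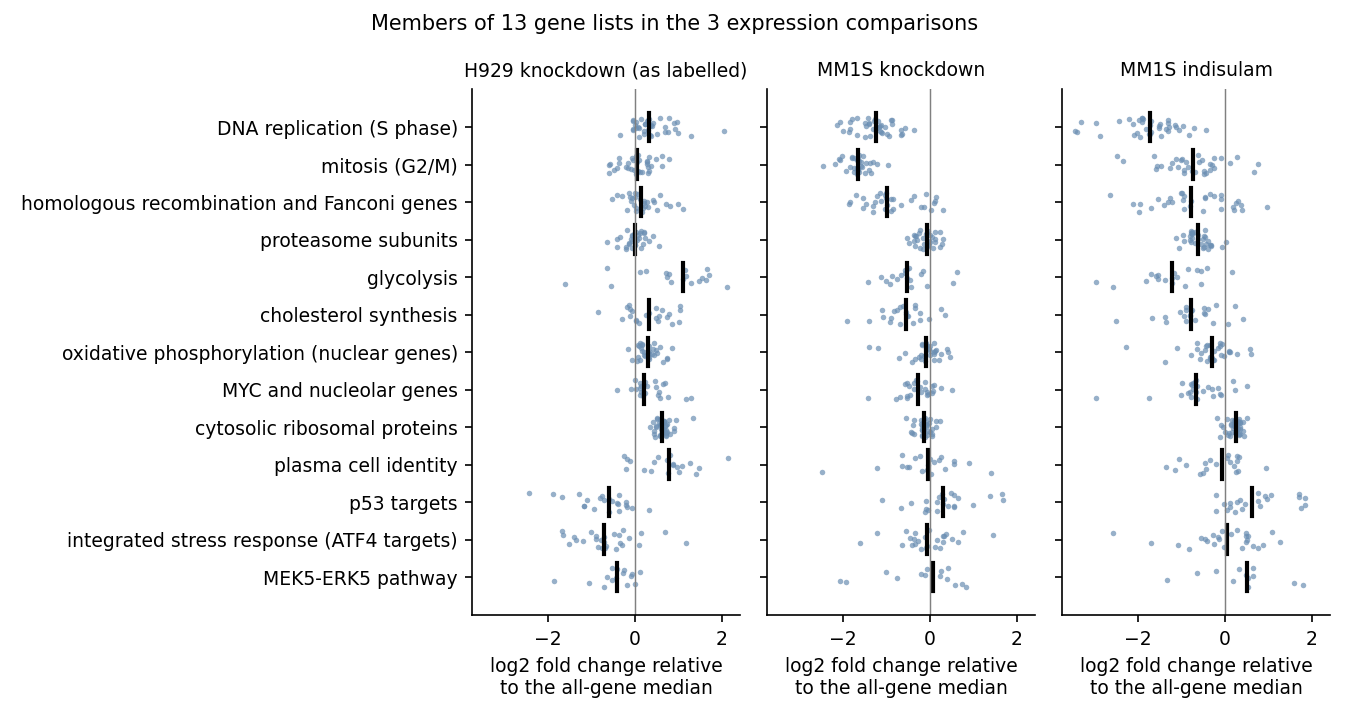
Log2 fold change relative to the median of all genes (x axis) of each tested member of 13 gene lists in the 3 comparisons, H929 as labelled; points are genes and black lines are list medians. The proteasome median was -0.62 with indisulam (28 of 32 called) and -0.07 in the MM1S knockdown (0 of 32 called by limma).

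Whether knockdown and drug moved the same genes in MM1S was tested by overlap. Among 12614 genes tested in both, 475 fell in both comparisons where 188.5 were expected for independent lists (Fisher's exact test, two-sided, p = 4.29e-109), and 141 rose in both where 38 were expected (p = 1.07e-45). Only 22 rose with knockdown and fell with indisulam, and 13 did the opposite. Across genes, the log2 changes correlated with r = 0.45 and rho = 0.41; genes are not independent replicates, so these values and the Fisher p describe the overlap only. Without indisulam replicate 3, 544 genes fell in both (249.3 expected) and 359 rose in both (196.9 expected). LGALS1, which encodes galectin-1, fell from 1360 to 193.8 TPM with knockdown and from 2128 to 369 TPM with indisulam. The cell cycle transcription factor gene MYBL2 fell from 159.4 to 32.3 TPM and from 105.5 to 11.9 TPM, and the histone chaperone gene ASF1B from 39.8 to 8.05 TPM and from 64.8 to 7.05 TPM. ALDH8A1 and ERMN rose in both. LGALS1, MYBL2 and ASF1B were picked from the genes called in both MM1S comparisons, a choice added after the values were seen.

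H929 as labelled went against MM1S. Of 848 genes called both in H929 as labelled and in the MM1S knockdown, 645 (76.1%) moved in opposite directions. Log2 changes over 9509 genes correlated with r = -0.34 and rho = -0.36. There were 385 genes higher in H929 as labelled and lower in MM1S, where 179 were expected (Fisher's exact test, two-sided, p = 2.06e-65), and 260 the other way, where 162.7 were expected (p = 1.3e-27). By contrast 173 were lower in both (352.1 expected) and 30 higher in both (82.7 expected). H929 as labelled against indisulam gave r = -0.27 and rho = -0.25 over 9358 genes, with 60% of 1994 shared calls in opposite directions. RRM2, the desaturase gene SCD and the tubulin gene TUBB were higher in the H929 libraries labelled shRBM39 and fell in both MM1S comparisons. TUBB was at 539.8 against 220.4 FPKM in H929 and fell from 777.8 to 295.1 TPM and from 395.4 to 78.8 TPM in MM1S. They belong to 295 genes called in both MM1S comparisons and in the opposite direction in H929 as labelled, 229 of them lower and 66 higher in MM1S, a group chosen after the values were seen. Called in the same direction in all 3 comparisons as labelled were 87 genes, 84 of them lower. These 84 are a small part of 464 genes with a proper symbol that fell in both MM1S comparisons, since 229 were higher in H929. Among the 9509 genes tested in H929 and the MM1S knockdown, 4524 were lower in H929, so some shared calls are expected. The mitotic kinase gene WEE1 was at 14.8 against 30.8 FPKM in H929 and fell from 44 to 17 TPM and from 17.3 to 7.69 TPM in MM1S. Others were the cytoskeletal gene VCL, the calcium-binding protein gene S100A6 and the origin recognition gene ORC6.

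**Figure D3:**
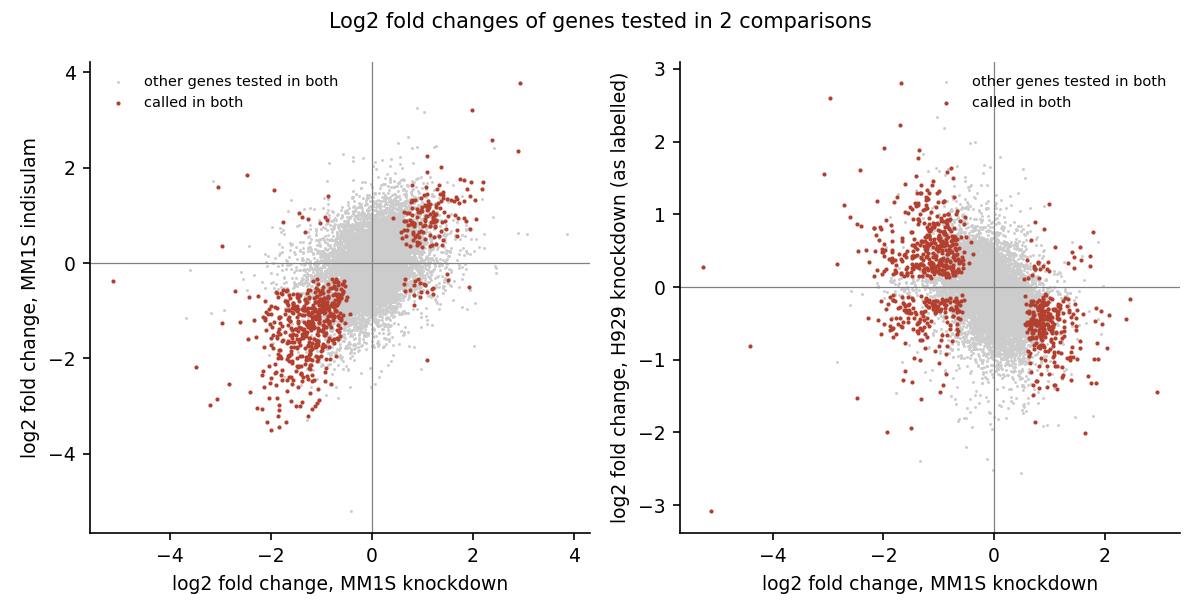
Log2 change per gene in the MM1S knockdown (x axis) against indisulam in MM1S (left, y axis) and against H929 as labelled (right, y axis); each point is a gene and red points were called in both. Changes went the same way in the left panel (r = 0.45) and in opposite ways in the right panel (r = -0.34).

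The RIP comparison asked which transcripts associate with RBM39 in MM1S. With 1 library per arm there are no replicates and no test. Of 10946 genes, 2478 were at least 2-fold higher in the RBM39 RIP than in IgG and 2614 at least 2-fold lower; after median scaling the counts were 2804 and 2344, so which side held more genes depended on the scaling. MAP2K5 was 11.6 FPKM with the RBM39 antibody and 11.7 FPKM with IgG, a log2 ratio of -0.01 at percentile 49.1 of all genes, and RBM39 transcript was 62.1 and 126.5 FPKM. The highest ratios were those of CRELD2, an ER stress gene, at 214 against 1.08 FPKM, SH2D4A, at 25.8 against 0.229 FPKM, the heat shock transcription factor gene HSF1, at 143.2 against 5.97 FPKM, and the chaperone gene HSPA1A, at 27.9 against 0.541 FPKM. SYK, SURF6 and LY75-CD302 were near 0 in IgG, and TRMT12 and ZNF408 were listed at 0 there. The lowest were MT-ND4, near 0 against 1397 FPKM, LUC7L2, near 0 against 104.6 FPKM, RPS17L, at 0.353 against 119.9 FPKM, METTL12, at 0.257 against 86.5 FPKM, and LY96, listed at 0 against 63.9 FPKM. Values near 0 for transcripts this abundant in the other library may be failed estimates, so these ratios are uncertain.

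Some gene groups had ratios far below those of random lists matched on expression only. The percentiles describe 1 library per arm and are no test. Mitochondrial genes took 0.39% of FPKM in the RBM39 library and 6.74% in IgG. Ribosomal protein genes had a median log2 ratio of -2.1, with 36 of 40 at least 2-fold lower, below all of 10000 random lists of matched expression (percentile 0). Mitochondrial transcripts had -4.76 (11 of 11 lower, percentile 0), oxidative phosphorylation genes -1.26 (18 of 32 lower, percentile 0) and histones -1.8 (14 of 17 lower, percentile 0.3). The highest percentiles among the fixed lists were those of RAS-ERK feedback targets, at 0.84 (percentile 97.9), BCL2 family genes, at 0.77 (96.8), and DNA replication genes, at 0.36 (95.9), and some random lists lay above each of them. The MEK5-ERK5 list lay at 0.15 (58.5), core splicing factors at -0.22 (23.8), proteasome genes at 0 (51.8) and mitosis genes at -0.54 (3.1). Genes that fell in the MM1S knockdown had a median of -0.13 (3.2) and those that fell with indisulam -0.07 (2.2), so neither group lay above its matched random lists. Genes lower in H929 as labelled had 0.15 (100) and those higher -0.13 (0). The other lists lay between percentiles 4.8, for the DCAF15 ligase, and 89.9, for glycolysis.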

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

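All tests of explanations in this part were chosen after the results were seen. Among RBM39, MAP2K5 and the genes named for the largest changes, those whose libraries all moved one way in H929 as labelled and all moved the opposite way in the MM1S knockdown were RBM39 (log2 2.81 and -1.69), MAP2K5 (-0.37 and 0.25), SCD (2.61 and -2.97), PPFIA4 (2.34 and -1.04), HPRT1 (2.23 and -1.70), CA9 (2.19 and -0.90), RRM2 (1.91 and -1.99), CDKN1A (-2.56 and 0.49), ALDH8A1 (-1.44 and 2.94), COX7C (-0.16 and 2.45), ERMN (-0.45 and 2.39) and PCLAF (1.56 and -3.07). These are 12 of the 18 such genes tested in both tables; genes named only as members of a list were not searched. The difference was not tested, since the tables were normalized separately. In H929 the median log2 difference of all genes tested was -0.134, so COX7C, at -0.16, lay close to that median. Directions here and in the share over all genes below were counted without removing this offset. MAP2K5 barely parted in the MM1S knockdown, with 9.36 TPM in scramble replicate 1 and 9.38 TPM in shRBM39 replicate 1. It did not pass the test there (limma adjusted p = 0.451). Over all 9509 genes in both tables, 4599 had groups without overlap in both, and 3195 of these (69.5%) went in opposite directions; chance alone gives non-overlap in 10% of genes for 3 against 3 libraries, as in H929, and in a share of 0.333 for 2 against 2, as in the MM1S knockdown.

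The pattern is RBM39 at 37.5 FPKM in the H929 libraries labelled shRBM39 and 4.5 FPKM in those labelled scramble. An error in the RBM39 entry alone is argued against by the other genes, since log2 changes in H929 and MM1S correlated with r = -0.33 when RBM39 was left out. Depth is argued against too, since the deepest H929 library had 1.15 times the depth of the first. Exchanged labels of the H929 groups are a candidate explanation. Of genes called both in H929 as labelled and in the MM1S knockdown, 76.1% moved in opposite directions, which an exchange predicts. The other 203 of 848 moved the same way, CCL4 among them (log2 -3.09 and -5.12). Mitosis genes did not reverse as a group. In the MM1S knockdown 33 of 34 fell, while in H929 as labelled 12 were higher and 14 lower (15 and 9 after median scaling). For the other genes, a true opposite response of H929 cells cannot be told apart from exchanged labels. H929 also ran against indisulam (r = -0.27), and the design has no second perturbation of H929. Such a response of other genes would not by itself account for RBM39, the target that the labels name, at 37.5 against 4.5 FPKM.

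The second pattern is indisulam replicate 3, apart from replicates 1 and 2. After median scaling, genes higher in replicates 1 and 2 lay 58.1% of the way back to DMSO (interval 55.3% to 60.6%). That interval comes from resampling genes, not libraries. The genes were chosen by their values in replicates 1 and 2, so part of the way back is expected from the choice alone. Within that limit, the authors' scaling of each library to the same total is argued against as the whole cause. RNA of untreated cells in replicate 3 may contribute, but the shares that 1093 higher and 778 lower genes would need, 88.7% and 0.7%, differed by 88 points as deposited and by 32.1 points after median scaling, where the sets were 700 higher and 1129 lower genes (58.1% and 26%), so a mixture with a scaling offset stays open. RNA quality cannot be told apart either: ribosomal protein genes took 29.01% of TPM against 21.17% to 23.01%, and 12550 genes were at 1 TPM or more against 13129 to 13751, while the mitochondrial share, 10.95%, lay within the range of the others. No biological explanation was tested.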

How the results depend on the processing

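The crossed replicate block, the fits without indisulam replicate 3 for lists and overlaps, and the settings for genes chosen after seeing the values were added later; all other alternatives were planned. In H929 the count of changed genes (7477) lay between 5498 and 8411 under every setting except a log2 change of at least 1, which gave 492; leaving out a library gave 7024 to 7427, and RBM39 stayed at 2.79 to 3.03 and MAP2K5 passed the test in every setting run. Of 85 named genes 84 to 85 kept their call in each setting that tested them all. In the MM1S knockdown the count of 1461 became 887 at a log2 change of at least 1, 0 with no filter (limma; 27260 genes tested, 4966 at an unadjusted p under 0.05), 255 with the replicate block and 772 with the crossed block, and 0 to 465 without 1 library (0 without scramble replicate 1, scramble replicate 2 or shRBM39 replicate 2, 465 without shRBM39 replicate 1); fewer libraries or more genes tested are part of these settings. RBM39 there was -1.69 with no filter (adjusted p = 0.0723; 0.00624 to 0.222 over its alternatives) and -1.84 to -1.54 without 1 library. Of 61 named genes all kept their direction, 61 lost the call with no filter and 27 with the block. With indisulam the count of 4024 became 1509 at a log2 change of at least 1 and 1849 to 9350 without 1 library (2045, 1974 and 1849 without DMSO replicate 1, 2 and 3; 9350 without indisulam replicate 3); the replicate block gave 3176, and 7530 in H929. RBM39 there was 0.40 after quantile normalization (adjusted p = 0.0387; 0.00899 to 0.966 over its alternatives) and -0.06 to 0.24 without 1 library, -0.03 without indisulam replicate 2 and -0.06 without replicate 1. MAP2K5 with indisulam was -0.32 to -0.16 without 1 library, passing only without replicate 3 (-0.32, adjusted p = 0.026; 0.026 to 0.532 over its alternatives); the cause was not tested. Of 84 named genes 71 to 84 kept the call in each setting that tested them all. SF3A2 turned to 0.04 in H929 after median scaling and SF3B2 to 0.06 with indisulam after quantile normalization; the cause was not tested. Gene lists passing went from 13 to 0 with an estimated correlation and 20 by fry in H929, from 6 to 0 and 0 in the MM1S knockdown, and from 10 to 0 with an estimated correlation for indisulam. Shared calls at a log2 change of at least 1 and with the block were 44 and 94 (higher in H929 as labelled, lower in MM1S knockdown), 16 and 23 (the reverse), 250 and 126 (lower in both MM1S comparisons) and 52 and 20 (higher in both); without indisulam replicate 3 the last was 359. At 4-fold the RIP counts were 646 and 978, from a stricter threshold. Depth is known only in relative terms for H929, so it sets no stated limit on low values.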

Other observations

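The 4 gene lists and the tests of explanations in this part were chosen after the values were seen. Genes induced by the hypoxia factor HIF, 9 of which are also in a list fixed earlier, fell with indisulam in 18 of 26 cases (camera p = 1.34e-08, p = 0.138 with an estimated correlation). PFKFB4 went from 9.13 to 0.657 TPM, ADM, which encodes adrenomedullin, from 279.3 to 82.9 TPM, and AK4 from 5.53 to 0.203 TPM. In the MM1S knockdown 1 of 27 fell (camera p = 0.0653), and in H929 20 of 25 were higher and 4 lower in the libraries labelled shRBM39 (camera p = 3.88e-09, p = 0.113 with an estimated correlation). Spliceosome genes, the core snRNP proteins and U2 factors, fell with indisulam in 16 of 22 cases (camera p = 3.43e-05, p = 0.029 with an estimated correlation), with SNRPF from 50.8 to 17.2 TPM, SNRPE from 205.3 to 91 TPM and SF3B3 from 100 to 41.9 TPM; 8 of the 22 are in the fixed splicing list. In the MM1S knockdown 1 of 22 members rose and no other passed, and in H929 as labelled 7 members were higher and 7 lower. The set test gave a camera p of 0.171 for the MM1S knockdown and of 0.314 for H929. These p-values are among 12 tests and are not adjusted. The spliceosome list had no set test without indisulam replicate 3 or after median scaling. The fixed splicing list had 16 lower and 15 higher members without that replicate, where 3959 of all genes were lower and 5391 higher. Genes called with indisulam and chosen after seeing the values kept their calls without it (45 of 45), but members newly called higher were not counted.

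Cytokine genes fell in the MM1S knockdown in 8 of 14 cases and rose in 1 (camera p = 8.17e-04, p = 0.194 with an estimated correlation), while with indisulam 5 of 10 rose and 3 fell (camera p = 0.0575) and in H929 as labelled 1 of 8 was higher and 6 lower (camera p = 0.0631). In MM1S these counts hold the paralogs CCL3 and CCL3L1, and CCL4 and CCL4L2, as separate genes, although reads may be shared between them. With indisulam CCL4 fell (log2 -0.382) while CCL4L2 rose (0.365). The chemokine gene CCL3 fell from 2857 to 504.6 TPM with knockdown and rose from 1221 to 4408 TPM with indisulam, and NR4A1 fell from 10.4 to 1.97 TPM and rose from 1.72 to 6.86 TPM. CYP26A1, which degrades retinoic acid, went the other way, from 20.7 to 45.3 TPM and from 95.9 to 22.9 TPM. These 3 are among 35 genes called in opposite directions in the MM1S comparisons; the difference was not tested. Fatty acid synthesis genes fell in 4 of 11 cases with knockdown (camera p = 0.00138, p = 0.269 with an estimated correlation) and in 4 of 12 with indisulam (camera p = 0.0282, p = 0.487 with an estimated correlation), with SCD from 74.4 to 9.31 TPM and from 163.4 to 68.6 TPM; in H929 as labelled 3 of 11 were higher and 5 lower (camera p = 0.704).

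The third pattern is the fall of 28 of 32 proteasome genes with indisulam. The authors' scaling of each library to the same total is argued against, since 24 of the 32 were called lower after median scaling. Slower proliferation stays open. In the MM1S knockdown the proteasome median was -0.07 (interval -0.19 to 0 from resampling genes, not libraries). The mitosis median there was -1.66, further down than the -0.72 with indisulam. However, the DNA replication median fell less far in the knockdown, -1.23 against -1.71. An effect of the drug on proteasome transcripts is a hypothesis from these data, and it may not extend beyond them. The camera call gave an adjusted p = 0.222 with an estimated correlation, where few residual degrees of freedom make small p-values hard to reach. Replicate 3 differs from the other indisulam libraries, but the fall does not rest on it. Without replicate 3, 30 of the 32 were lower and 1 higher, with a relative median of -0.69.

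For H929 the real split gave 7477 genes, the highest of the other splits gave 0, and 1 of the 10 splits, the real one, gave as many. For indisulam the real split gave 4024 genes, the highest other gave 3, and 1 of the 10 splits, again the real one, gave as many. In both, 10 splits are too few for a share under 0.05.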
